A study of Danio rerio with 2 samples.

How the data were processed

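Liver samples of zebrafish on a high-fat diet were compared between wild type and an ambp knockout, with 1 library each. Per the labels' protocols, total RNA was taken with TRIzol, mRNA was enriched with oligo(dT) beads and fragmented, and libraries were made with the NEBNext Ultra RNA kit. HISAT2, featureCounts and the genome build GRCz11 are named in the submitters' processing notes, without versions or roles. The authors deposited estimated counts per gene, per the file headers named as counts, which were not whole for 5.45% of genes in the wild-type column and 6.01% in the knockout column. How the fractions arose is not given in the sources used here. The authors also deposited FPKM values, per the file headers. The gene length implied by the count, the FPKM and the column total was the same within 5% in both libraries for 86.9% of 7665 genes with at least 1 FPKM in both, and how the others were scaled is not given in the sources used here. Of the file's sample columns, 4 were used and 0 were left unmatched to a sample. The table held 25939 genes, of which 25197 had Ensembl identifiers and 742 were assembled loci without one, which took 1.01% of the wild-type and 0.872% of the knockout counts.

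Estimated counts were rounded to whole numbers first. Gene symbols came from an Ensembl name table, matched by identifier for 23499 of the 25939 genes, and the symbol in the deposited table was kept beside them. Where several genes carry the same symbol, the identifier is given, and their values are uncertain, since paralogs can share reads. Gene order around ambp was taken from the RefSeq table of GRCz12tu, used only for names and neighbours. A genome of the submitters' build was not used here, so no positions are given.

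Library sizes were scaled with TMM factors of 0.916 for wild type and 1.09 for the knockout, from edgeR 4.0.16 in R 4.3.3. DESeq2 1.42.0 gave size factors of 0.842 and 1.19 for the alternative scaling. Levels are CPM computed with these sizes. The log2 ratios of knockout over wild type used a pseudocount of 1 CPM, which understates the ratio of low genes. Genes with at least 1 CPM in either library were kept, 11634 in all. One read equalled 0.0697 CPM in wild type and 0.0499 CPM in the knockout. Folds are ratios of CPM with no pseudocount. Intervals for single genes are exact Poisson intervals for levels and exact conditional binomial (Clopper-Pearson) intervals for ratios, at 95%. Intervals for medians of lists came from a bootstrap over genes. For a gene with 0 reads in a library, a floor of 3 reads there was used only to give an at-least fold. Its log2 ratio used 0 reads and the pseudocount. The size rule was 2-fold on the log2 scale, and no test across genes was made.

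The gene lists of the report, its comparisons, most of the other settings tried and the rule for named genes were fixed before the data were examined; tests and alternatives added later are named as such where they are given. There were 44 lists. Listed names were matched to the table's names by hand afterwards, from names alone and before any list value was computed. The ribosomal list was a name pattern that also took in S6 kinase genes. For each list with at least 5 measured members, which was 40 lists, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and called at or beyond percentiles 2.5 and 97.5, as a description of these libraries. Named genes were ambp, the 12 genes with the largest ratios upward and the 12 downward among genes with a proper symbol and at least 100 reads in a library. Also named were the 2 most abundant and the 2 most different members of each list, members of the PPAR, oxidation, antioxidant, oxidase and inter-alpha-trypsin lists, and the 5 genes with most counts in a library. These last were apoa2, tfa, apoa1b, mt-co1 and apoc1 in both, with 20.4% of the wild-type and 20.3% of the knockout counts together. The 20 most counted genes took 39.4% and 37.9%. Some genes that this rule names are not reported here.

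Alternatives were other scalings, pseudocounts, filters, fold thresholds, an added counting interval, the mean in place of the median, lists without shared members and the deposited FPKM. The scaling that leaves out the 20 top genes was rescaled to a common size after its first output was seen, because smaller denominators had inflated CPM. An alternative with random lists matched on this implied length was chosen after seeing the data. The methods were tested on simulated data drawn from the real means and sizes. In simulated pairs, 4-fold changes passed the rule in 100%, 98% and 89% of 100 genes at assumed coefficients of variation of 0, 20 and 40%. Changes of 1.5-fold passed in 0%, 16% and 37% of 100 genes. The changed genes were drawn only from genes at 10 CPM or more over both libraries pooled. The 4-fold and 1.5-fold rates describe these genes and were not split by level. They need not hold for low genes, whose ratios the pseudocount understates. Of 100 unchanged lists of 20 random genes, 3, 6 and 6 were called, and lists shifted by 0.5 were called 100, 100 and 71 times. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.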

Results

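Poly(A) RNA was sequenced from the livers of zebrafish (Danio rerio) fed a high-fat diet, from wild-type fish and from fish without a working ambp gene, with 1 library per genotype. The gene ambp encodes the precursor that is split into alpha-1-microglobulin, a heme-binding and reductant plasma protein, and bikunin, the shared subunit of the inter-alpha-trypsin inhibitors. The wild-type library held 15659846 estimated reads and the knockout library 18357830, and 17347 and 18080 genes had at least 1 read. The number of fish behind each library is not given in the sources used here. There were no replicates, so the differences have no replicate check, no p-value is given, and all values describe these 2 libraries. Intervals for levels and ratios of single genes are 95% intervals that cover counting error only. Intervals given later for medians of lists come from a bootstrap over genes and do not cover variation between fish.

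The targeted gene was far lower in the library labelled as knockout. Expression of ambp (ENSDARG00000004296) was 3506 CPM (3475 to 3536) in the wild-type liver, from 50280 reads, and 154 CPM (149 to 159) in the knockout, from 3085 reads. The knockout level was 4.39% of the wild-type level, a 22.8-fold difference (22.0 to 23.6). Among the 11634 genes with at least 1 CPM in either library, ambp ranked 2 from the lowest log2 ratio, which carries a pseudocount of 1 CPM; by fold without it, low-count genes such as grik1, slc25a38 and ddit4 lay lower. The heavy chains that bikunin is joined to did not follow it, since itih2 had a log2 ratio (knockout over wild type) of 0.18, itih3a.1 of -0.12, itih3b.1 of 0.50 and itih3b.2 of 0.41. With ambp included, the 5 measured inter-alpha-trypsin genes had a median of 0.18 and a mean of -0.71, so the sign depended on the summary, and the median lay at percentile 92.0 of 10000 random lists of the same size and expression.

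The comparison asks how the loss of ambp changes liver expression on this diet. By a 2-fold size rule, 628 genes were higher and 744 lower in the knockout library, 11.8% of those measured. Scaling by library total in place of TMM moved the median log2 ratio of all genes to 0.22 and turned the split to 1071 higher and 485 lower, which is 68.8% higher against 45.8%, so the balance of directions is not fixed by these data. In simulated pairs of libraries, 124 of 11204 unchanged genes passed the 2-fold rule at an assumed between-animal coefficient of variation of 20%, and 1736 of 11267 at 40%, more than the 1372 observed.

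**Figure D1:**
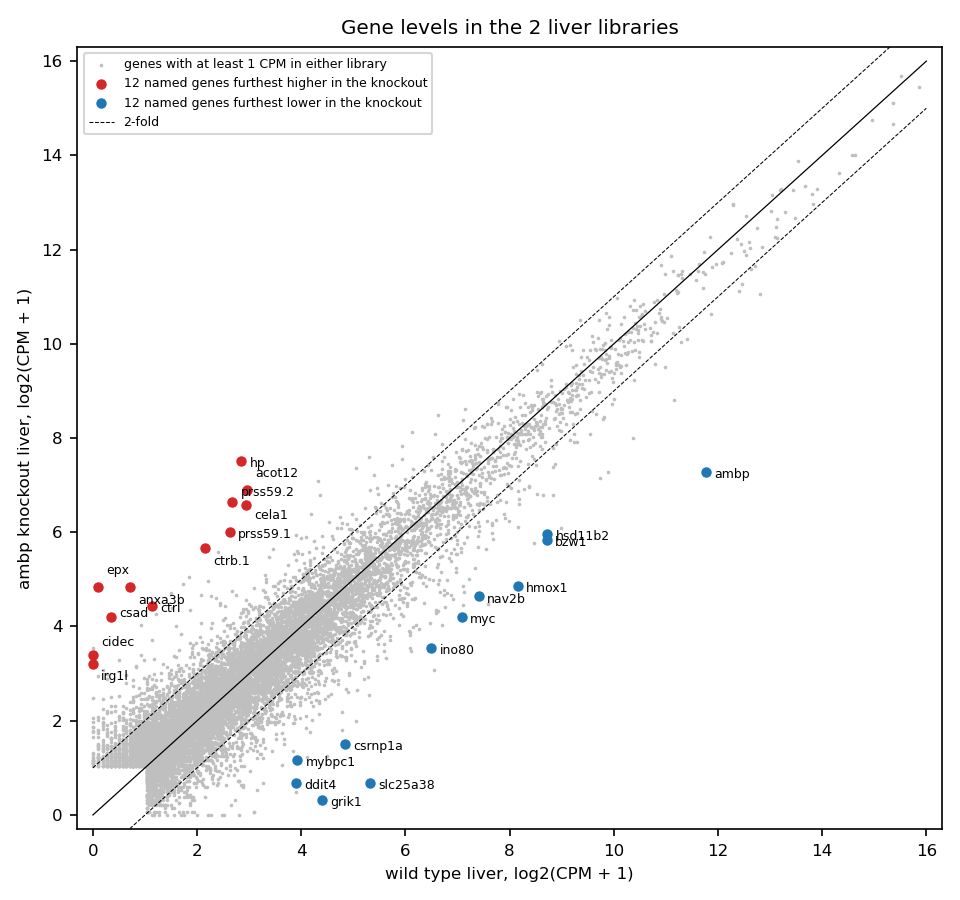
Each point is 1 of 11634 genes, with log2(CPM + 1) in the wild-type liver on the horizontal axis and in the ambp knockout liver on the vertical axis; red and blue points are the 12 named genes furthest higher and lower, the solid line marks equal levels and the dashed lines a 2-fold difference. The blue ambp point lies at 3506 CPM in wild type and 154 CPM in the knockout, and across genes the log2 levels had a Pearson correlation of 0.945, which says nothing of replicates.

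The 12 named genes furthest higher in the knockout by log2 ratio included 4 of the exocrine pancreas list. The peroxidase gene epx (ENSDARG00000019521, named Mpo in the deposited table) had 1 read in wild type and 556 in the knockout, a ratio of 398 (71.1 to 15743). Haptoglobin, hp (ENSDARG00000051890), which binds free hemoglobin, was 29.2-fold higher (23.6 to 36.4), at 6.21 against 181 CPM. The annexin anxa3b was 44.0-fold higher (23.0 to 96.8), the acyl-CoA thioesterase acot12 17.6-fold (14.3 to 21.7) and csad, of taurine synthesis, 62.4-fold (24.2 to 230.4). The lipid-droplet gene cidec had 0 reads in wild type and 192 in the knockout, which is at least 45.8-fold higher when 3 reads are taken as the floor in a library, though its counting interval reaches down to 36.9-fold. By the same floor irg1l, with 0 and 166 reads, was at least 39.6-fold higher, with an interval down to 31.8-fold. The remaining 5 were cela1 and the pancreas list's prss59.2, ctrb.1, prss59.1 and ctrl.

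The 12 named genes furthest lower by log2 ratio included ambp, hmox1, ddit4 and myc. The mitochondrial carrier slc25a38 (ENSDARG00000059805) was 64.9-fold lower and the glutamate receptor gene grik1 80.5-fold lower, on 12 and 5 reads in the knockout. Heme oxygenase, hmox1 (ENSDARG00000027529), was 10.1-fold lower, from 285 to 28.2 CPM. The stress gene ddit4 was 23.3-fold lower, csrnp1a 14.9-fold, the transcription factor gene myc (ENSDARG00000007241) 7.72-fold and hsd11b2, which inactivates cortisol, 6.86-fold. The other 5 were ino80, bzw1, nav2b, mybpc1 and, as already given, ambp.

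Fatty acid oxidation genes were higher in the knockout library as a group. Of 22 mitochondrial beta-oxidation genes, 20 had log2 ratios above 0, 2 were at least 2-fold higher and none was 2-fold lower. The median of 0.46 lay above all 10000 random lists, at percentile 100. Very-long-chain acyl-CoA dehydrogenase, acadvl, had 2021 and 7886 reads (log2 ratio 1.47). A form of the enzyme that admits fatty acids to mitochondria, cpt1ab, had 995 and 3231 reads. The member with the most reads in wild type, cpt1b, had -0.61, and acadm, with the most in the knockout, had 0.27. Among 19 peroxisomal oxidation genes the median was 0.34 (percentile 99.8), with acox3 at 1.42 and crot at 1.07 among those past 2-fold and catalase, cat, at 0.40. In the same list ehhadh had -0.20.

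PPAR signaling genes did not move one way. This list was chosen because the study names the pathway, so its direction is not independent evidence. Of 55 members, 5 were at least 2-fold higher, 6 at least 2-fold lower and 44 between. The median of 0.06 lay at percentile 95.8, inside the central range of random lists. Higher members were the lipid-droplet coat gene plin2 (1.58), fabp4a (1.36), the already named cpt1ab, acsl4 (1.16, ENSDARG00000004078) and rxra (1.08, on 4 and 34 reads). Lower members were pck1, of gluconeogenesis (-2.60), the glycerol channel aqp7 (-2.18), lipoprotein lipase, lpl (-1.25), apoa1a (-1.05) and 2 genes sharing the name cyp8b1 (-1.15 and -1.11), which are uncertain because near-identical copies can share reads. The receptors themselves were pparaa at 0.92, pparg just under the 2-fold rule on 23 and 84 reads, and ppard at 0.15 and 0.99 in its 2 copies, all from 895 reads or fewer in a library. Without the members that other lists also hold the percentile was 99.8, and with the deposited FPKM it was 100, so the call depended on these choices.

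Genes of reactive oxygen species handling did not share a direction. This theme too was chosen because the study names it. Among 35 antioxidant genes the median was 0.02 (percentile 85.9) and the mean -0.04, with 3 higher and 2 lower by 2-fold. By that rule hmox1 (-3.29) and gsta.1 (-1.32) were lower, and nfe2l2 (1.04), gpx1b (1.37) and keap1 (1.44) higher, the last 2 on at most 95 reads. Abundant members were cat and gpx4a, at 0.40 and 0.78. Of 8 measured NADPH oxidase genes, 7 had ratios above 0 and the median was 0.79 (percentile 99.9), or 0.35 relative to all genes with a pseudocount of 5 CPM. These were low-abundance genes, such as ncf1 with 22 and 96 reads, nox5 with 67 and 195, rac2 with 66 and 190 and cybb with 42 and 126. Macrophage markers, with a median of 0.73, and neutrophil markers, with 0.60, were higher in the same library, and several of these oxidase genes are used by phagocytes.

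**Figure D2:**
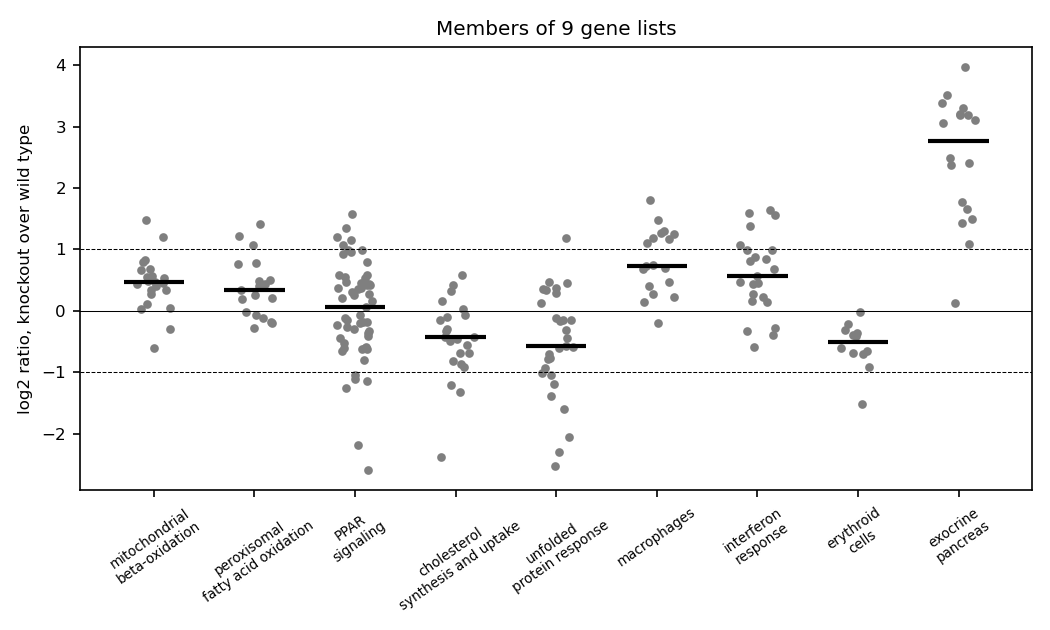
Points are single genes of 9 lists, with the log2 ratio of knockout over wild type on the vertical axis; thick bars are list medians and dashed lines mark 2-fold. Exocrine pancreas genes lie highest (median 2.77), beta-oxidation genes mostly above 0 (0.46), and unfolded protein response (-0.58) and cholesterol (-0.42) genes mostly below 0.

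Cholesterol synthesis and uptake genes were lower. The median over 23 members was -0.42 (percentile 0.27), and 18 of them had ratios below 0. The low-density lipoprotein receptor gene ldlra had 19012 reads in wild type and 5080 in the knockout (-2.38), and tm7sf2, of sterol synthesis, was at -1.32, while idi1 stood at 0.15. This call was lost with the 10 CPM filter (percentile 5.97) and with FPKM (5.78). With a pseudocount of 5 CPM the cholesterol median was -0.21 relative to all genes, still called. The other lipid lists lay inside the random range. De novo lipogenesis had a median of -0.05 (percentile 55.4), with fasn at -2.21 and acly (ENSDARG00000099079) at 2.32. Lipoprotein assembly had a median of -0.18 and a mean of 0.01, with apoa4a at -1.35, tm6sf2a at 1.38 and the abundant apoa2 and apoa1b at -0.41 and -0.26. Lipid droplet genes had a median of 0.24 (percentile 94.5).

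Unfolded protein response genes were lower and proteasome genes higher. The response list, of endoplasmic reticulum chaperones and stress regulators, had a median of -0.58 over 29 genes (percentile 0.01), with 8 genes at least 2-fold lower and 1 higher. With a pseudocount of 5 CPM the median was -0.30 relative to all genes, still called. The chaperone hspa5 had 955 reads in wild type and 214 in the knockout (log2 ratio -2.53), hyou1 414 and 102 (-2.29), chac1 was at -2.06, and the abundant pdia3 was at 0.33. The proteasome had a median of 0.33 over 34 genes (percentile 99.99), 28 of them above 0, with psmb6 at 1.08 and psmd1 at 0.99. Immediate-early genes had a median of -0.42 (percentile 0.585), with cebpd at -1.58 and dusp1 at -0.95, a call lost with no filter (-0.16 relative to all genes, percentile 12.7). Lysosome and autophagy genes had 0.23 (percentile 98.6), with ulk1a at -1.57, a call lost with the 10 CPM filter (percentile 96.5) and with FPKM (94.8). Heat shock genes had 0.23 (percentile 96.7), with hsp90ab1 at 0.79 and hspa8 at 0.48, and apoptosis genes a median of 0.20 and a mean of -0.16 (percentile 93.9), with gadd45b at -2.32.

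All 13 protein-coding mitochondrial transcripts were lower in the knockout, from -0.57 for mt-co2 to -1.48 for mt-nd4l, with a median of -0.79 (percentile 0.01). They took 13.2% of the wild-type counts and 9.47% of the knockout counts. Nuclear genes of oxidative phosphorylation had a median of -0.04 (percentile 82.3), with atp5f1b at -0.03 and sdhb, the member furthest lower, on 265 and 175 reads.

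Markers of macrophages and neutrophils and interferon-responsive genes were higher in the knockout library. Macrophage markers had a median of 0.73 (percentile 100), with 8 of 18 at least 2-fold higher and none lower, such as grna.1 (1.80) and csf1ra (1.48, on 10 and 75 reads). Neutrophil markers had 0.60 over 8 genes (percentile 99.0), 6 above 0 and 2 below. Among them epx was at 4.75, lyz at 2.15 and the abundant srgn and il6r at 0.50 and 0.22. Only 5 of the 8 reached 1 CPM in wild type, so the rest passed the filter through the knockout library alone. The call was lost with the 10 CPM filter (percentile 90.9), and with no filter the median was 0.30 above that of all genes. Interferon-responsive genes had 0.57 over 23 genes (percentile 99.99), with isg15 at 1.64 (204 and 932 reads) and mxc at 1.59. Relative to all genes this median was 0.34 with a pseudocount of 5 CPM and 0.94 with the 10 CPM filter, both called. Of the 23 genes, 19 reached 1 CPM in wild type. The cytokine and NF-kB list had a median of 0.05 (percentile 61.4), with nfkbie at 1.58 and socs3 (ENSDARG00000025428) at -1.56, and acute-phase and complement genes had -0.01 (percentile 88.9) and a mean of 0.06. Within that list hp and the iron regulator hamp (246 and 1653 reads) were higher. Heme and iron genes had a median of 0.34 (percentile 99.5), with hp at 4.66 and hmox1 at -3.29 at its ends, and tfa, of iron transport, at 0.17. That call was lost with no filter (percentile 95.7) and with the 10 CPM filter (95.3).

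Markers of other tissues also differed. Of 18 exocrine pancreas genes 17 were at least 2-fold higher, with a median of 2.77 (percentile 100), and together they took 0.00533% of the wild-type and 0.0514% of the knockout counts. Among them prss59.2 was at 5.37 CPM in wild type and 98.7 CPM in the knockout. Endocrine pancreas genes were too few for a percentile, and ins had 1 and 65 reads and gcga 2 and 64. Erythroid genes were lower, with a median of -0.51 (percentile 0.8), hbaa1 at -0.91 and all 12 below 0. Biliary genes had 0.32 (percentile 98.3), with krt18a.1 at 1.11 and the abundant krt8 at -0.02, a call lost in 7 of 11 other settings. Cell cycle genes had -0.36 over 18 genes (percentile 0.66), with mcm5 at -1.30 and pcna at 0.12. With FPKM this list's median was 0.020 above that of all genes. Relative to all genes it was -0.13 with a pseudocount of 5 CPM and -0.63 with 0.1 CPM. Endothelial genes (0.07, percentile 56.4) and stellate and matrix genes (0.08, percentile 65.0) lay inside the random range, as did intestine genes (-0.34, percentile 6.88). Only 3 lymphocyte genes, 2 ovary genes and no skeletal muscle gene were measured.

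**Figure D3:**
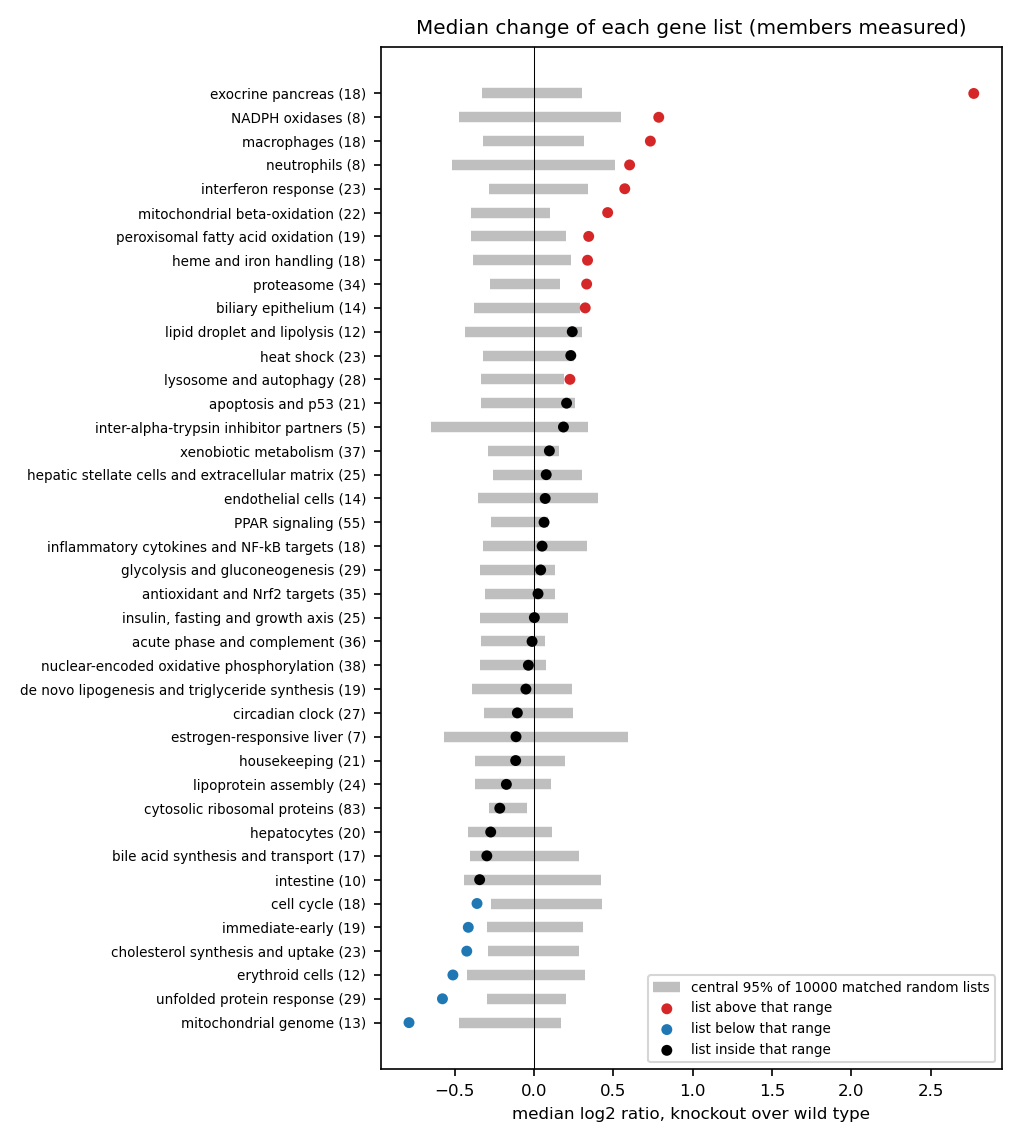
Points give the median log2 ratio (knockout over wild type) of 40 gene lists, with the number of measured members in brackets, and gray bars the central 95% of medians of 10000 random lists matched on expression. There are 11 lists above the gray bars and 6 below, with exocrine pancreas furthest above (2.77) and the mitochondrial genome furthest below (-0.79).

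The other lists lay inside the random range. Hepatocyte genes had a median of -0.27 (percentile 18.99), with a1cf at 548 and 3839 reads, cebpa at -1.31 and the most abundant, apoa2, at -0.41. Estrogen-responsive genes had a median of -0.11 and a mean of 0.21 (percentile 32.8), with vtg4 at 1.93 on 3 and 72 reads. Bile acid genes had -0.30 (percentile 9.14), with abcc2 at 0.54, and without the 9 of 17 members that other lists hold the median was 0.21 above that of all genes. Glycolysis and gluconeogenesis genes had a median of 0.04 and a mean of -0.08 (percentile 88.6), with g6pc1 at -1.75. The insulin, fasting and growth list had a median of 0.00 and a mean of -0.30 (percentile 67.9), with ddit4 at -3.22 and sesn1 at -1.71. Xenobiotic genes had 0.10 (percentile 93.2), with cyp2k22 at -2.36, and clock genes -0.11 (percentile 29.2), with per1 (ENSDARG00000056885) at -1.57. Housekeeping genes had -0.12 (percentile 43.3), with hprt1 at -1.67 and actb2 at -1.31, and cytosolic ribosomal protein genes -0.22 (percentile 16.6). Of the 40 lists with a percentile, 17 lay outside the central 95%, where lists of random genes would place 2 on average. Genes within a list can vary together between any fish, so 2 is not a chance rate for these lists.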

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

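The test with length-matched lists was chosen only after the data were seen, and the scaling without the top 20 genes was rescaled after its first output was seen; the other settings were set beforehand. List values here are medians less the median of all genes in that setting, and 10 of the 17 called lists kept their call in all settings that gave a value. Library totals moved the all-gene median to 0.22, leaving out the top 20 genes to 0.19 and FPKM to 0.19. The ambp log2 ratio was -4.25 with library totals, -4.28 without the top 20 genes and -4.25 with FPKM. Genes higher and lower by the size rule numbered 1071 and 485 with library totals, 1279 and 1212 with a pseudocount of 0.1 CPM, 151 and 319 with 5 CPM, 227 and 433 with the 10 CPM filter, 1904 and 1971 at 1.5-fold and 59 and 91 at 4-fold; 1014 were higher without the top 20 genes and 358 lower with FPKM. Other thresholds and filters count other genes by construction, and for the rest the cause was not tested. Calls were lost for biliary genes with library totals (0.29), without the top 20 genes (0.29), with 5 CPM (0.16), no filter (0.082), the 10 CPM filter (0.37), FPKM (0.11) and length matching (0.32). They were also lost with no filter for heme and iron (0.15) and immediate-early genes (-0.16), with the 10 CPM filter for cholesterol (-0.35), heme and iron (0.27), neutrophil (0.60) and lysosome genes (0.25), and with FPKM for cholesterol (-0.23) and lysosome genes (0.17). Lists newly called were intestine (-0.34) and heat shock (0.16) with no filter, PPAR (0.29), lipid droplet (0.45), cytokine (0.35) and glycolysis (0.18) with FPKM, lipid droplet with the mean (0.38) and PPAR without shared members (0.36). Cell cycle genes, a called list, changed sign with FPKM (0.020), and acute-phase genes changed sign and were called with the mean (0.072). In all, 16 of 40 lists changed sign in some setting. They included, without a call, bile acid genes without shared members (-0.30 to 0.21), apoptosis genes with the 10 CPM filter (0.21 to -0.26) and PPAR (0.065 to -0.043) and insulin and fasting genes (0.0038 to -0.11) with no filter. With a pseudocount of 5 CPM, which shrinks ratios of low genes by construction, 9 called lists kept their call at values smaller by over 1.5 times: exocrine pancreas (1.76), oxidase (0.35), interferon (0.34), neutrophil (0.33), heme and iron (0.18), cell cycle (-0.13), immediate-early (-0.18), cholesterol (-0.21) and unfolded protein response genes (-0.30). Other settings moved called values that much for neutrophil (1.001 with 0.1 CPM, 0.30 with no filter, 1.14 with the mean), cell cycle (-0.63 with 0.1 CPM), peroxisomal (0.23 with no filter), interferon (0.94) and immediate-early (-0.99, both with the 10 CPM filter), and heme and iron genes (0.52 with the mean and without shared members). The 10 CPM filter left the oxidase, endothelial, cell cycle and estrogen-responsive lists under 5 members, as FPKM did the last, so these gave no value. Alternatives for files without counts or with replicate columns were not run, since the file had counts and 1 column per group. No paired analysis was possible because each group had 1 library. Depth limits genes of few reads, such as the cell cycle list, whose members had at most 117 reads in a library.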

Other observations

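The tests on scaling and the random lists set beside the pancreas correlation were chosen only after the result was seen. So were the endothelial, erythroid, length-matched and fasting-gene values and the search for genes seen almost only in a single library. The correlation of pancreas genes and the test of genes beside ambp were set before those were computed. Values of 4 of the pancreas genes had then been seen. Lipid synthesis genes differed in both directions within a list that lay inside the random range. Besides fasn (-2.21), acaca (-2.20) and lpin1 (-2.04) were lower in the knockout library, while elovl6 (1.87), which lengthens fatty acids, was higher along with acly (2.32, ENSDARG00000099079). Lipid droplet genes included cidec, seen in the knockout alone, plin2 (1.58) and the lipase gene mgll (612 and 2457 reads), against lpl (-1.25) and pnpla2 (-1.02). Here acaca, lpin1, elovl6, mgll and pnpla2 were chosen after their values were seen.

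There were 8 genes with at least 100 reads in a library and at most 2 in the other, 6 of them with the reads in the knockout. These were epx, c6ast3, cidec, irg1l, an unnamed clone gene (148 against 2 reads) and a locus that the deposited table names RBBP6 (213 against 0). A further 2 loci of that name went the other way, each with 108 reads in wild type against 1 in the knockout. No named symbol was held by 4 of the 8, against 9.42% of the 6370 genes with 100 reads. The 40 measured genes nearest ambp in the RefSeq order of GRCz12tu had a median absolute log2 ratio of 0.50, at percentile 83.7 of matched random lists, so as a set they did not stand apart. Within the set, ptgdsa, beside ambp, was at 1.42 and anxa3b, 21 genes away, at 4.14. A median over the set cannot exclude an effect of sequence carried along with the mutation on single genes such as these. By the 2-fold rule 2 of the set were higher and 2 lower, the lower being si:busm1-57f23.1 (-1.48) and mtrex (-1.09).

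Exocrine pancreas genes were higher in the knockout library by a median of 2.77. Scaling does not account for it, since the lowest median over the 3 other scalings was 2.76. Pancreatic tissue carried into the knockout sample is a hypothesis that these values leave open: across the 18 genes, levels in both libraries had a Spearman correlation of 0.72, but 1000 random lists matched on expression had a median of 0.82 (central 95% 0.61 to 0.93), so the correlation favours no source. Members ranged from pla2g1b, with 250 and 384 reads, to prss59.2, with 77 and 1979, and ins and gcga had 65 and 64 reads against 1 and 2. The list shares no gene with the other lists, 14 of its members reached 1 CPM in the wild-type liver too, its most abundant gene was prss59.2 at 98.7 CPM, and an effect of the genotype on pancreas was not tested.

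Macrophage genes were higher by a median of 0.73. A lower share of hepatocytes would raise markers of other resident cells alike. The endothelial median lay 0.66 below the macrophage median (difference -0.66, bootstrap interval over genes -1.15 to -0.34). Biliary genes had a median of 0.32, stellate and matrix genes 0.08 and hepatocyte genes -0.27, and no interval was computed for these. More blood in the knockout sample would raise erythroid genes, whose median was -0.51 (bootstrap interval over genes -0.69 to -0.33). Open hypotheses include more macrophages, more expression per cell, or a difference between fish unrelated to genotype, which 1 library per group cannot separate. Whether tissue carried into the knockout sample, left open for the pancreas genes, adds macrophage transcripts was not tested. Of the 18 genes none is in another list and 16 reached 1 CPM in wild type.

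Beta-oxidation genes were higher by a median of 0.46. Gene length does not account for it, since the list stayed at percentile 100 when random lists were matched on length too. A longer fast before sampling would be a candidate explanation. A list of 11 fasting-induced genes, written after pck1 and ddit4 had been seen, had a median of -1.28 (bootstrap interval over genes -1.75 to 0.001). That interval reaches 0, so these genes do not decide on a longer fast, and only a longer fast was examined. With 1 library per group, a difference in feeding and an effect of the genotype cannot be told apart here. An effect of ambp loss on fatty acid oxidation is therefore one hypothesis among these.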
